A study of Mus musculus with 2 samples.

How the data were processed

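RNA sequencing was carried out by the submitters on adult mouse cerebellum, in 2 libraries that form a single group. Per the labels, the libraries are strand-specific and paired-end with reads of 101 bases, from polyadenylated RNA longer than 200 nucleotides after ribosomal RNA depletion, with spike-in RNAs added. Per the file headers and the accompanying index, each library was quantified against the mm10 assembly with GENCODE annotation M4 from transcriptome alignments. The column names are those that RSEM writes, and the aligner and the versions are not given in the sources used here. The authors deposited for each gene and transcript an expected count, which is an estimated number of fragments that need not be whole, a TPM value that is relative to all entries including spike-ins and tRNA genes, and an FPKM value. They also deposited for each transcript its percent of the gene's TPM, and a posterior mean version of TPM. Expected counts were rounded to whole numbers before any count model.

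A separate set of files covers the whole series on the mm9 assembly. Per the file headers, which here are the attribute names, the deposited RPKM values are given for replicates numbered 1 and 2 per Ensembl 65 gene, transcript and exon, and per gene assembled by Cufflinks. These numbers name no library. The deposited junction table gives read counts over each splice junction and, in its names, the reads of each replicate, and the deposited contig table gives a coverage signal and the aligned bases of each contig over both replicates together. Both deposited tables also hold a fraction between 0 and 1, the authors' irreproducibility value, which was not used here as a filter. The aligner and quantification program of the mm9 tables are not given in the sources used here. Values of the mm9 and mm10 assemblies were never combined by coordinate, only by gene identifier without its version. The assembled exons and transcripts of the mm9 set were not used here.

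Gene names, classes and coordinates came from GENCODE M21, which is on the same assembly as mm10, by identifier without version; 42462 of 43346 genes (98.0%) matched. Total expected counts were 83109117 in replicate 1 and 84279927 in replicate 2. Genes took 96.0% and 95.3%, ERCC spike-ins 2.85% and 2.95%, and the phiX control sequence 1.16% and 1.80%. The 26248 tRNA entries held 1 and 2 counts. The 95% Wilson intervals of these shares and of the mitochondrial shares were at most 0.00516 percentage points to either side, and those of shares of junctions and introns at most 0.172. Spike-in, phiX and tRNA entries were left out of library sizes and of all gene counts, but stay in the denominator of the authors' TPM.

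The gene lists (cell types, programs and gene families), the rule for genes named in the text and the results to be reported were fixed before the data were examined. Named genes are the 15 highest by mean TPM among mitochondrial and among nuclear genes, up to 4 highest members and the lowest member of each list, members of the fixed families, the genes chosen for isoforms, and the 10 with the largest ratio between replicates in each direction. Some genes that this rule names are not reported here, but they stay in the lists and counts. A list's level is the median over its members of the mean TPM, set against 10000 random lists of the same size drawn from protein-coding genes. Lists hold markers that other cells of the tissue can also express, and some genes are in more than 1 list. The 2 libraries were compared with log2 CPM from edgeR 4.0.16 in R 4.3.3 after TMM scaling, with a prior count of 2, for genes with at least 100 counts over both libraries, or 10 for list members. The number of genes at least 2-fold apart was set against 100 Poisson draws at the same depths. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept only. A list was said to stand apart when its median log2 ratio was outside the central 95% of 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. No p-values were computed, since one group of 2 libraries allows no test of a condition. A fold against a library with no counts was computed against a floor of 3 counts in that library. The 95% interval for Xist is an exact Poisson interval on its smaller count.

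The comparison of replicates was tested on counts simulated for 15543 genes at the real means and library sizes. All changed genes of 4-fold (100%) and 45.0% of genes changed exactly 2-fold passed the 2-fold threshold, against 0.00652% of unchanged genes, and a simulated coefficient of variation of 0.100 came back as 0.101. In a separate step on 15534 simulated genes that reached the count minimum, with 200 lists of 12 genes, 3.50% of unchanged lists and 88.5% of lists shifted by 0.250 on the log2 scale stood apart. The simulated genes varied independently, so these shares do not cover lists whose genes move together.

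A junction was matched to an annotated intron when chromosome, both ends and strand were identical, with introns taken as the gaps between exons of each Ensembl transcript. Contigs and assembled loci were compared with annotated genes by overlap of at least 1 base (bedtools 2.31.1), contigs with regard to strand and assembled loci without. Alternatives were DESeq2 1.42.0 size factors, spike-in totals and TPM ratios in place of TMM, other filters, pseudocounts and thresholds, FPKM, TPM rescaled without spike-ins and mitochondrial genes, leaving out each replicate, the mm9 values, and a lowess correction for GC content and length with a span of 0.300. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.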

Results

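The transcriptome of the adult mouse cerebellum was measured by RNA sequencing of 2 libraries from C57BL/6J mice aged 8 weeks. C57BL/6J is the standard inbred laboratory strain. The libraries came from separate tissue samples, numbered by the submitters as biological replicates 1 and 2, and both are labelled as pooled tissue of males and females from mixed-sex littermates. They share one donor record, so nothing given states that they came from separate animals or litters. Both belong to a single group, cerebellum, and the design holds no contrast between conditions. The measurements therefore describe which genes, cell type markers, receptor families and isoforms the tissue expresses, and how far the 2 replicates differ. Replicate 1 held 83109117 estimated fragments and replicate 2 held 84279927, of which 79771873 and 80281011 were assigned to annotated mouse genes. Values written as mean ± SD are over the 2 libraries (n = 2), in TPM, a length-corrected relative abundance, as the authors computed them unless another unit is given, and coordinates are those of the mm10 assembly unless mm9 is named. Intervals and floors cover counting error only.

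Of 43346 annotated genes, 14477 reached 1 TPM in both libraries. Protein-coding genes made up 13074 of these, processed pseudogenes 369, antisense genes 224 and long intergenic non-coding RNAs 209. The most abundant nuclear-encoded messenger RNAs were Mbp, which encodes myelin basic protein (ENSMUSG00000041607.12, mm10 chromosome 18, positions 82475146 to 82585637), at 3921 ± 435 TPM; the glycolytic enzyme gene Gapdh at 3519 ± 411 TPM; the ferritin heavy chain gene Fth1 at 3451 ± 503 TPM; the brain creatine kinase gene Ckb at 3232 ± 244 TPM; and the ubiquitin gene Ubb at 2627 ± 310.4 TPM. Several short or repeated non-coding entries lay above them. Gm42418, which overlaps a ribosomal RNA repeat on chromosome 17, stood at 14272 ± 1639 TPM, the 7SK small nuclear RNA Rn7sk at 10165 ± 2284 TPM, and the signal recognition particle RNA genes Rn7s2 and Rn7s1 at 5035 ± 495 TPM and 4342 ± 825 TPM. A cluster of 6 unprocessed pseudogenes on chromosome 1 between positions 24612407 and 24616197 also ranked among the 15 highest nuclear genes: Gm29216 at 12754 ± 491 TPM, Gm28437 at 5268 ± 456 TPM, Gm10222 at 4884 ± 397 TPM, Gm10925 at 4403 ± 516 TPM, Gm28661 at 4112 ± 1771 TPM and Gm28438 at 2119 ± 165 TPM. These are nuclear copies of mitochondrial sequence, so their values are uncertain because reads can be shared with the mitochondrial genome, and the 7SL and ribosomal entries are uncertain because of their own repeated copies.

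Genes of the mitochondrial chromosome held 5.70% of gene counts in replicate 1 and 5.93% in replicate 2. Among them mt-Co1, a catalytic subunit of cytochrome c oxidase, reached 20109.8 ± 273 TPM, mt-Co2 14285 ± 581 TPM, mt-Co3 13916 ± 340.5 TPM, mt-Atp6 9595 ± 465 TPM and mt-Cytb 9419.8 ± 26.3 TPM, down to 1099 ± 159 TPM for mt-Nd4l, the lowest of the 13 protein-coding members. In TPM the mitochondrial share was 20.05% and 23.0%. Most of the gap between the count and TPM shares lay in mt-Atp8 (ENSMUSG00000064356.3, mm10 chromosome M, positions 7766 to 7969), a subunit of ATP synthase, which held 10.4% and 13.3% of TPM from 0.102% and 0.118% of gene counts. The authors' table gave this transcript of 204 nucleotides an effective length of 14.8 in replicate 1 and 12.7 in replicate 2. Nuclear genes of oxidative phosphorylation had a list median of 408 TPM, with Cox4i1 at 1824 ± 33.9 TPM, Atp5b at 1415 ± 45.8 TPM, Ndufa4 at 1044 ± 2.03 TPM and Cycs, encoding cytochrome c, lowest at 44.5 ± 0.672 TPM. Glycolytic genes had a median of 551 TPM, with Aldoc at 1707 ± 61.6 TPM, Aldoa at 1593 ± 111 TPM and Pkm at 1359 ± 58.2 TPM, and Pfkl lowest at 64.5 ± 5.26 TPM.

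Markers of the cerebellar cortical neurons were among the most abundant of the 21 cell type lists, 10 of which had a median of 10 TPM or more. The 18 granule neuron genes had a median of 145 TPM (159 in replicate 1 and 130.2 in replicate 2), above all 10000 random lists drawn from protein-coding genes, and all 18 reached 1 TPM in both libraries. Zic1, a zinc finger transcription factor, stood at 778 ± 95.2 TPM, but 60.4% of its TPM was in a processed transcript of 395 nucleotides without an annotated coding sequence. Cbln1, a secreted synaptic organiser of the parallel fibres, was at 612 ± 95.9 TPM, and its relative Cbln3 at 378 ± 54.8 TPM. Gabra6, the GABA-A receptor subunit typical of granule cells (ENSMUSG00000020428.9, mm10 chromosome 11, positions 42306437 to 42321072), stood at 303 ± 47.1 TPM, and the transcription factor gene Barhl1 was lowest at 7.96 ± 0.00707 TPM. The 16 Purkinje neuron genes had a median of 121 TPM, above all 10000 random lists. Pcp2, a Purkinje cell protein (ENSMUSG00000004630.14, mm10 chromosome 8, positions 3623371 to 3625545), was highest at 1467 ± 167 TPM, followed by Pcp4 at 845 ± 31.5 TPM, the carbonic anhydrase-related gene Car8 at 255 ± 40.1 TPM and the inositol trisphosphate receptor gene Itpr1 at 244 ± 30.7 TPM, with Foxp2 lowest at 3.46 ± 0.361 TPM.

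The 15 genes of GABAergic interneurons had a median of 31.1 TPM, led by Pvalb, which encodes the calcium buffer parvalbumin, at 654 ± 17.5 TPM, the GABA-synthesising enzyme gene Gad1 at 336 ± 46.9 TPM and the vesicular transporter gene Slc32a1 at 141 ± 3.60 TPM. Purkinje cells also express several of these. Deep cerebellar nuclei had a list median of 26.5 TPM, with the neurofilament genes Nefm at 172 ± 43.6 TPM and Nefh at 151 ± 30.8 TPM, Sncg at 94.8 ± 11.6 TPM and Spp1 at 88.4 ± 12.6 TPM, while Tbr1 was at 0.315 ± 0.0919 TPM. Unipolar brush cells, a small excitatory interneuron of the granular layer, had a median of 5.74 TPM, at percentile 52.3 of the random lists. Its highest members, Calb2 at 351 ± 5.07 TPM and Plcb4 at 115 ± 14.2 TPM, are also made by granule or Purkinje neurons, and Lmx1a was at 0.770 ± 0.0707 TPM.

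Glial genes reached the highest list median. The 14 oligodendrocyte genes had a median of 292 TPM, above all 10000 random lists, with Mobp at 865 ± 111 TPM, the transferrin gene Trf at 645 ± 48.7 TPM and Opalin lowest at 26.1 ± 2.67 TPM. Oligodendrocyte precursors had a median of 11.6 TPM over 9 measured genes, with Olig1 at 136 ± 15.9 TPM, Sox10 at 46.9 ± 4.21 TPM, Olig2 at 21.5 ± 2.00 TPM and Cspg4 lowest at 3.21 ± 0.240 TPM. The astrocyte list had a median of 133 TPM, led by Glul, which encodes glutamine synthetase, at 883 ± 7.10 TPM, Atp1b2 at 594 ± 41.5 TPM and S100b at 492 ± 11.2 TPM, besides Aldoc. Bergmann glia, the radial astrocytes of the Purkinje cell layer, had a median of 77.0 TPM, with Sept4 at 643 ± 17.0 TPM, the glutamate transporter gene Slc1a3 at 263 ± 38.2 TPM, Hopx at 164 ± 19.4 TPM and Timp4 at 154 ± 14.7 TPM, down to 1.11 ± 0.608 TPM for Wif1. Sept4 is also in the oligodendrocyte list.

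Vascular, immune and blood markers differed widely in level. Endothelial genes had a median of 12.5 TPM, with Ly6c1 at 108 ± 3.38 TPM, the glucose transporter gene Slc2a1 at 93.7 ± 4.57 TPM and the tight junction gene Cldn5 at 43.3 ± 3.10 TPM, and mural cell genes one of 7.15 TPM, with Vtn at 92.0 ± 1.48 TPM and Rgs5 at 40.3 ± 5.18 TPM. Microglial genes had a median of 9.54 TPM, with the complement gene C1qb at 28.5 ± 1.61 TPM, Ctss at 26.5 ± 1.12 TPM and Aif1 lowest at 1.99 ± 0.905 TPM. Leukocyte genes had a median of 0.700 TPM. Red cell genes had a median of 70.7 TPM that rested on globins: Hba-a2 at 457 ± 242 TPM, Hbb-bs (ENSMUSG00000052305.5, mm10 chromosome 7, positions 103826534 to 103828096) at 446 ± 223 TPM, Hba-a1 at 199.6 ± 108 TPM and Hbb-bt at 85.3 ± 53.6 TPM, whose near-identical copies can share reads.

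**Figure D1:**
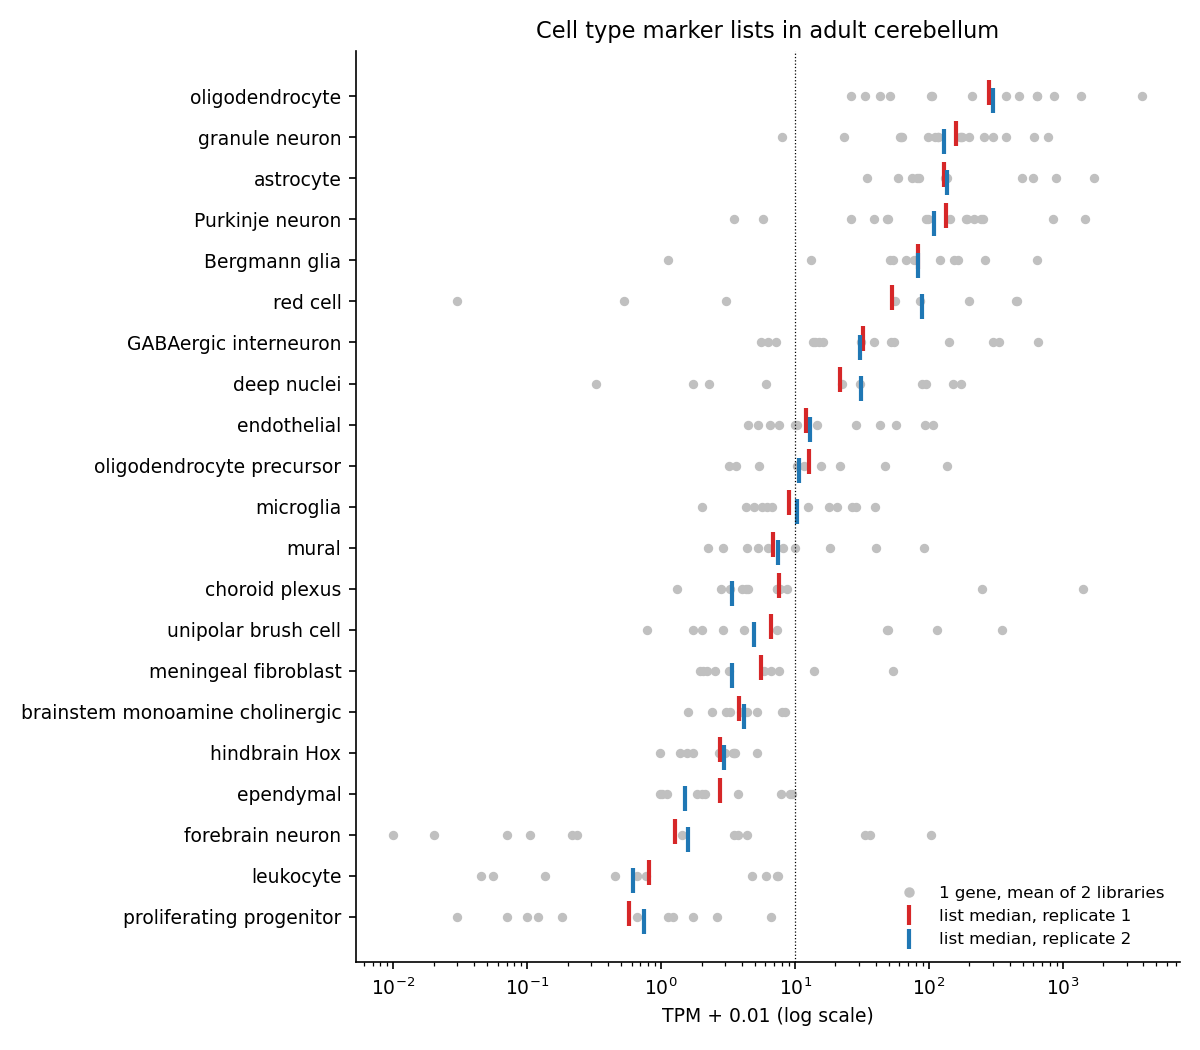
Levels of 21 cell type marker lists, on a log axis of TPM + 0.01. Grey points are genes (mean of 2 libraries), red and blue bars the list medians in replicates 1 and 2, and the dotted line marks 10 TPM; oligodendrocyte, granule neuron, astrocyte and Purkinje neuron lists have medians of 292, 145, 133 and 121 TPM.

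Markers of structures next to the cerebellum and of other brain regions were mostly low, with single abundant genes. Ttr, the transthyretin gene of the choroid plexus epithelium (ENSMUSG00000061808.3, mm10 chromosome 18, positions 20665280 to 20674321), was at 1425 ± 935 TPM and Enpp2 at 248 ± 80.9 TPM, while the median of the 12 choroid plexus genes was 5.89 TPM (7.61 in replicate 1 and 3.36 in replicate 2) and Folr1, Kcnj13 and Prlr were at 8.62 ± 5.01 TPM, 7.72 ± 5.95 TPM and 1.30 ± 0.608 TPM. Ependymal genes had a median of 2.04 TPM (2.74 and 1.49), with the ciliogenesis regulator gene Foxj1 at 9.54 ± 1.03 TPM, and meningeal fibroblast genes one of 4.50 TPM (5.57 and 3.37), with Igf2 at 54.0 ± 16.2 TPM and Dcn at 13.9 ± 2.47 TPM. Forebrain neuron genes had a median of 1.41 TPM. Among them Ppp1r1b, which Purkinje cells also express, was at 104 ± 13.2 TPM, Nrgn at 36.2 ± 7.97 TPM and Camk2a at 33.0 ± 0.905 TPM. Brainstem monoamine and cholinergic genes had a median of 4.07 TPM, with Slc18a3 at 8.36 ± 0.997 TPM and Th at 7.93 ± 1.37 TPM, hindbrain Hox genes one of 2.87 TPM, at percentile 36.9 of the random lists, with Hoxb5 at 5.19 ± 1.24 TPM, and proliferating progenitor genes one of 0.650 TPM, with Gli1 at 6.64 ± 1.20 TPM and the granule progenitor gene Atoh1 at 0.0200 ± 0.0141 TPM.

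Members of several receptor and channel families differed widely in level. Of the 16 GABA-A receptor subunits, Gabra6 and Gabrd, at 172 ± 26.0 TPM, exceeded Gabrb2 at 42.0 ± 6.75 TPM, while Gabra5 was at 9.86 ± 2.34 TPM and Gabrr1 at 0.210 ± 0.0141 TPM. Among AMPA receptors Gria4, Gria1, Gria2 and Gria3 were at 104 ± 13.0, 91.8 ± 9.14, 85.9 ± 7.45 and 38.3 ± 1.10 TPM. The NMDA receptor genes Grin1, the obligatory subunit, and Grin2c stood at 185 ± 8.22 and 172 ± 19.96 TPM, far above Grin2a at 8.34 ± 0.297 TPM and Grin2b at 3.12 ± 0.247 TPM. Grm4 led the metabotropic receptors at 201 ± 40.6 TPM, and Grm5 was at 5.61 ± 0.643 TPM. The delta receptor gene Grid1 was at 8.25 ± 0.396 TPM. Glycine receptor genes ranged from 121 ± 1.22 TPM for Glrb to 0.585 ± 0.0495 TPM for Glra3. The vesicular glutamate transporter genes Slc17a7 and Slc17a6 were at 259 ± 40.6 and 22.6 ± 4.09 TPM, and Slc1a6, the glutamate transporter of Purkinje cells, at 98.1 ± 7.94 TPM. Cacna1a, the pore of P/Q-type calcium channels, was at 154 ± 21.9 TPM and Cacna1g at 145 ± 26.1 TPM, against 7.50 ± 0.566 TPM for Cacna1h. The Kv3 potassium channel gene Kcnc1 was at 231 ± 11.2 TPM, and Kcnb2 at 1.05 ± 0.0283 TPM. The sodium channel alpha subunit genes Scn2a, Scn8a and Scn1a were at 66.7 ± 8.22, 63.7 ± 0.219 and 51.2 ± 0.368 TPM.

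Transcription factors that pattern the hindbrain were present at uneven levels. Besides Zic1, Zic2 was at 111 ± 15.8 TPM, Zic4 at 26.7 ± 4.24 TPM and Zic5 at 18.7 ± 1.77 TPM. The Engrailed and Pax list had a median of 3.90 TPM, at percentile 40.3 of the random lists, with 2 of 8 genes at 10 TPM or more. Pax6 was at 60.5 ± 9.87 TPM and En2 at 53.3 ± 10.1 TPM, while En1 was at 2.21 ± 1.02 TPM and Gbx2 at 1.21 ± 0.141 TPM. Of the synaptic vesicle release genes, Snap25 was at 1883 ± 36.4 TPM, Vamp2 at 442 ± 23.1 TPM and Vamp1 at 409.7 ± 63.4 TPM, with Stx1a at 7.67 ± 0.148 TPM. The synaptotagmin genes Syt11, Syt2 and Syt1 were at 288 ± 21.9, 201 ± 0.990 and 139 ± 10.3 TPM. Camk2b, at 321 ± 25.5 TPM, exceeded Camk2a. Neurexin genes Nrxn2 and Nrxn3 were at 289 ± 45.8 and 67.1 ± 4.04 TPM.

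Transcript estimates showed which isoforms carried this expression. Among 8102 genes with 5 TPM or more in both libraries and at least 2 annotated transcripts, the second most abundant transcript held at least 20% of the gene's TPM in both libraries for 3160 genes (39.0%). The leading transcript held a median of 67.3% and was the same in both libraries for 94.4% of genes. Snap25 was nearly all Snap25-201 (99.4 ± 0.120%), Gfap Gfap-201 (91.9 ± 0.148%), Camk2b Camk2b-209 (87.7 ± 0.0778%), the pyruvate kinase gene Pkm Pkm-202 (87.4 ± 0.170%) and Mbp Mbp-211 (76.8 ± 1.05%). Pcp2 was shared by Pcp2-203 (48.4 ± 0.0990%), Pcp2-205 (25.8 ± 0.311%) and Pcp2-201 (20.2 ± 0.764%), and the adhesion gene Nrcam by Nrcam-201 (62.6 ± 0.240%) and Nrcam-202 (37.4 ± 0.240%). Gria4-202 (52.0 ± 0.325%) and Gria4-201 (35.7 ± 0.0919%), of equal length, split the AMPA receptor gene Gria4. For Zic1 the leading transcript, Zic1-203 (60.4 ± 1.12%), is a processed transcript of 395 nucleotides without an annotated coding sequence, and 715 protein-coding genes in all were led by a transcript not annotated as protein-coding. The protein-coding Zic1-202 and Zic1-201 have 2811 and 5606 nucleotides. Shares are of length-corrected TPM, so a short transcript can lead with fewer fragments than a longer one. The leading share differed between libraries by a median of 2.36 percentage points and by up to 10.7 points in 95% of genes. Among the chosen genes Calb1-201 (58.9% and 69.7% in replicates 1 and 2) lay beyond that, and Map2-202 (28.2% and 38.5%) within it. Grin1-207, which did not lead its gene, held 6.84% and 16.9%. Rbfox1-202 held 54.8% and 46.2%, so which of the 2 Rbfox1 transcripts led depended on the library. The count of genes with such a second transcript depends on the thresholds, being 1222 at a share of 30% and 5412 at 10%.

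Replicate 1 and replicate 2 were then compared gene by gene. Across 23885 genes above 0 in at least 1 library, log2(TPM + 1) correlated between them with Pearson r 0.995 and Spearman rho 0.981; genes are not independent replicates, and no p-value is given. Among 15543 genes with at least 100 counts over both libraries, the median size of the log2 ratio was 0.09, and the biological coefficient of variation was 0.0947. The libraries were not one library deposited under 2 names: the chi-square of their counts was 29.6 per degree of freedom, and its median over genes 3.17. A total of 99 genes (0.637%) were at least 2-fold apart, 67 higher in replicate 1 and 32 higher in replicate 2, where Poisson draws at the same depths gave a mean of 0.140 and at most 2 over 100 draws. With the ratio of TPM + 1 in place of TMM-scaled counts, 37 genes were 2-fold apart, 18 higher in replicate 1 and 19 in replicate 2.

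**Figure D2:**
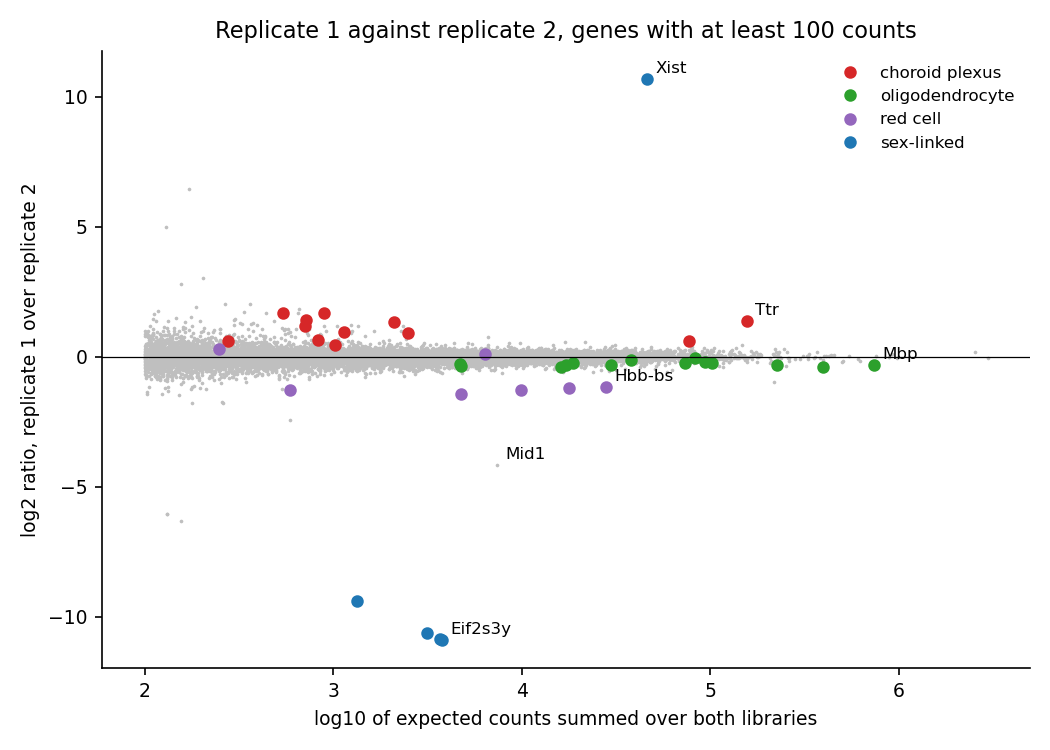
Log2 ratio of TMM-scaled CPM, replicate 1 over replicate 2, against the log10 of summed expected counts for 15543 genes. Coloured points are members of 4 lists; Xist lies at 10.69 with 45928 and 26 counts, Ttr at 1.39 and Hbb-bs at -1.16, and the 4 Y-linked genes, which had no counts in replicate 1, are placed by the prior count.

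Sex-linked transcripts accounted for the largest differences in each direction. Xist, the non-coding RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, mm10 chromosome X, positions 103460366 to 103483254), had 45928 counts in replicate 1 and 26 in replicate 2, so its level in replicate 2 was 0.0562% of that in replicate 1 (95% exact Poisson interval on the 26 counts, 0.0367 to 0.0823%). The Y-linked genes Eif2s3y (ENSMUSG00000069049.7, mm10 chromosome Y, positions 1010543 to 1028847), Ddx3y, Kdm5d and Uty had 0 counts in replicate 1 and 3776, 3662, 3124 and 1328 in replicate 2. Over these 4 genes, a count of 0 allows replicate 1 up to 0.0254% of the level in replicate 2. Against a floor of 3 counts per library, Eif2s3y was at least 1249-fold, Ddx3y at least 1211-fold, Kdm5d at least 1033-fold and Uty at least 439-fold higher in replicate 2. Both libraries carry the label of pooled male and female tissue. Kdm5c, an X-linked gene known to escape X inactivation and chosen after its values were seen, was higher in replicate 1 by 0.46 on the log2 scale, while 524 other X-linked genes had a median log2 ratio of -0.000106 and 14883 autosomal genes one of -0.00119. Mid1, an X-linked ubiquitin ligase gene at the boundary of the pseudoautosomal region (ENSMUSG00000035299.12, mm10 chromosome X, positions 169685199 to 170005736), was higher in replicate 2, with 382 and 6966 counts (-4.17), as was G530011O06Rik, which lies within the span of Mid1, with 91 and 501 counts (-2.42).

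**Figure D3:**
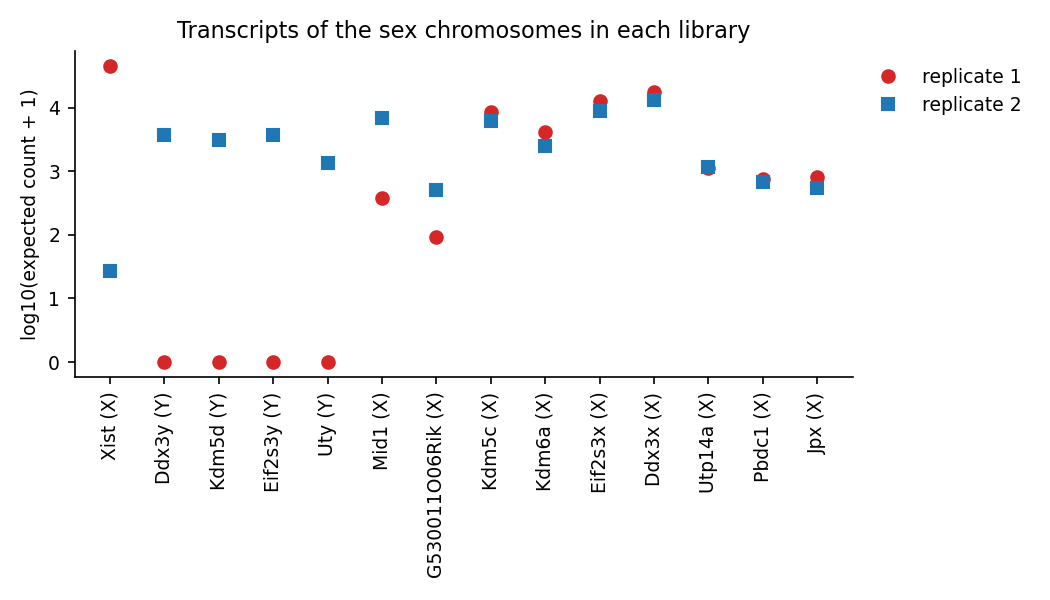
Expected counts of sex-chromosome genes in each library, as log10(count + 1), with the chromosome in brackets. Eif2s3y, Ddx3y, Kdm5d and Uty are at 0 counts in replicate 1, and Xist is at 45928 in replicate 1 and 26 in replicate 2.

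Several autosomal genes and a further gene of the Y chromosome also differed strongly. Htr5b, a serotonin receptor gene, had 137 counts in replicate 1 and 18 in replicate 2 (log2 ratio 2.81), the transcription factor gene Pou4f1 215 and 51 (2.04), and the lactate transporter gene Slc16a8 92 and 26 (1.76). Col6a4, a collagen gene, had 39 and 139 counts (-1.77), and Gm29650, a non-coding gene of the Y chromosome, was at least 51.6-fold higher in replicate 2. Further genes at either end have estimated counts that are not whole, as where reads are shared with copies or overlapping genes, and their values are uncertain. They were Gm2004, at least 57.4-fold higher in replicate 1, Tmem254c (5.01), Gm10163 (3.02), Trpc2 (1.93) and 2210418O10Rik (1.84), and in the other direction the processed pseudogenes Gm10240 and Gm13370, which had the same 132 counts and were each at least 43.5-fold higher in replicate 2.

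Choroid plexus, ependymal and meningeal marker lists were higher in replicate 1 as whole groups. All 12 choroid plexus genes were higher in replicate 1, with a median log2 ratio of 1.07, above all 10000 matched random lists; Ttr was at 1.39, Enpp2 at 0.62, Folr1 at 1.19 and Kcnj13 at 1.69. All 10 ependymal genes (0.65) and all 10 meningeal fibroblast genes (0.43) were likewise higher in replicate 1. Of the red cell genes 5 of 7 were higher in replicate 2, with a median of -1.19. Hba-a2 was at -1.19, Hbb-bs at -1.16, Hba-a1 at -1.28 and Hbb-bt at -1.44. Deep nuclei genes were higher in replicate 2 in 8 of 10 cases, with a median of -0.46, including Nefm (-0.59) and Nefh (-0.49), as were the brainstem monoamine and cholinergic genes (-0.21; 8 of 10).

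Smaller differences ran through the main cell types. All 18 granule neuron genes were higher in replicate 1 (median 0.23), including Gabra6 (0.22) and Cbln1 (0.27), as were 15 of 16 Purkinje neuron genes (median 0.21), the genes of the Zic list (0.26) and 7 of 8 calcium channel genes (0.17). The median was 0.18 for Bergmann glia. All 14 oligodendrocyte genes were higher in replicate 2 (median -0.29), including Mbp (-0.30) and Mobp (-0.33), as were all 12 microglial genes (-0.18), all 10 mural genes (-0.20), 7 of 9 precursor genes (-0.22) and 24 of 26 ribosomal protein genes (-0.13). Lipid synthesis genes of myelin such as Scd2 (-0.16) had a median of -0.11, neurotransmitter transporter genes one of -0.15, with Slc6a5, the neuronal glycine transporter, at -0.55, and 9 of 9 replication-dependent histone genes compared were higher in replicate 1 (0.42, or 0.29 for the 5 with at least 100 counts). Messenger RNAs of such histones mostly lack poly(A) tails, and other RNAs without them were also higher in replicate 1: Rn7sk (0.44), Rn7s1 (0.38), Rn7s2 (0.19) and Gm42418 (0.17). The class of miscellaneous RNA, with 0.178% and 0.138% of gene counts, is mostly Rn7sk, Rn7s1 and Rn7s2 and adds no separate evidence. A difference in RNA selection between the libraries was not tested. Engrailed and Pax genes had a median of 0.23. By TPM ratio some of these medians were smaller: -0.10 for microglia, -0.11 for mural cells, -0.06 for precursors, -0.11 for brainstem genes, -0.06 for ribosomal proteins, -0.06 for lipid synthesis and -0.04 for transporters, while TPM moved the median of all genes by 0.06. In all, 28 of 48 lists lay outside the central 95% of matched random lists, 13 higher in replicate 1 and 15 in replicate 2. Lists of genes drawn independently would give 2.40. Members of a fixed list can move together and lists share members, so 2.40 is no chance expectation for these lists. The count describes a pair of libraries and is no test of a condition. Within that range lay the astrocyte (-0.06), endothelial (-0.08), Hox (-0.10), leukocyte (-0.04), forebrain neuron (-0.01) and proliferating progenitor (-0.14) lists, and the sign for astrocytes, leukocytes and forebrain neurons changed with the scaling. Of these the endothelial list lay outside the range by TPM ratio (-0.07) and the forebrain neuron list by mm9 RPKM (0.22). Unipolar brush cell (0.18), GABAergic interneuron (0.08), GABA-A (-0.09), kainate and delta (0.11), glycine (-0.27), Kv channel (-0.09) and mitochondrially encoded (-0.06) lists did not stay outside that range under every alternative. The last lay within it after a GC and length correction and had a ratio of 0.0057 by TPM.

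**Figure D4:**
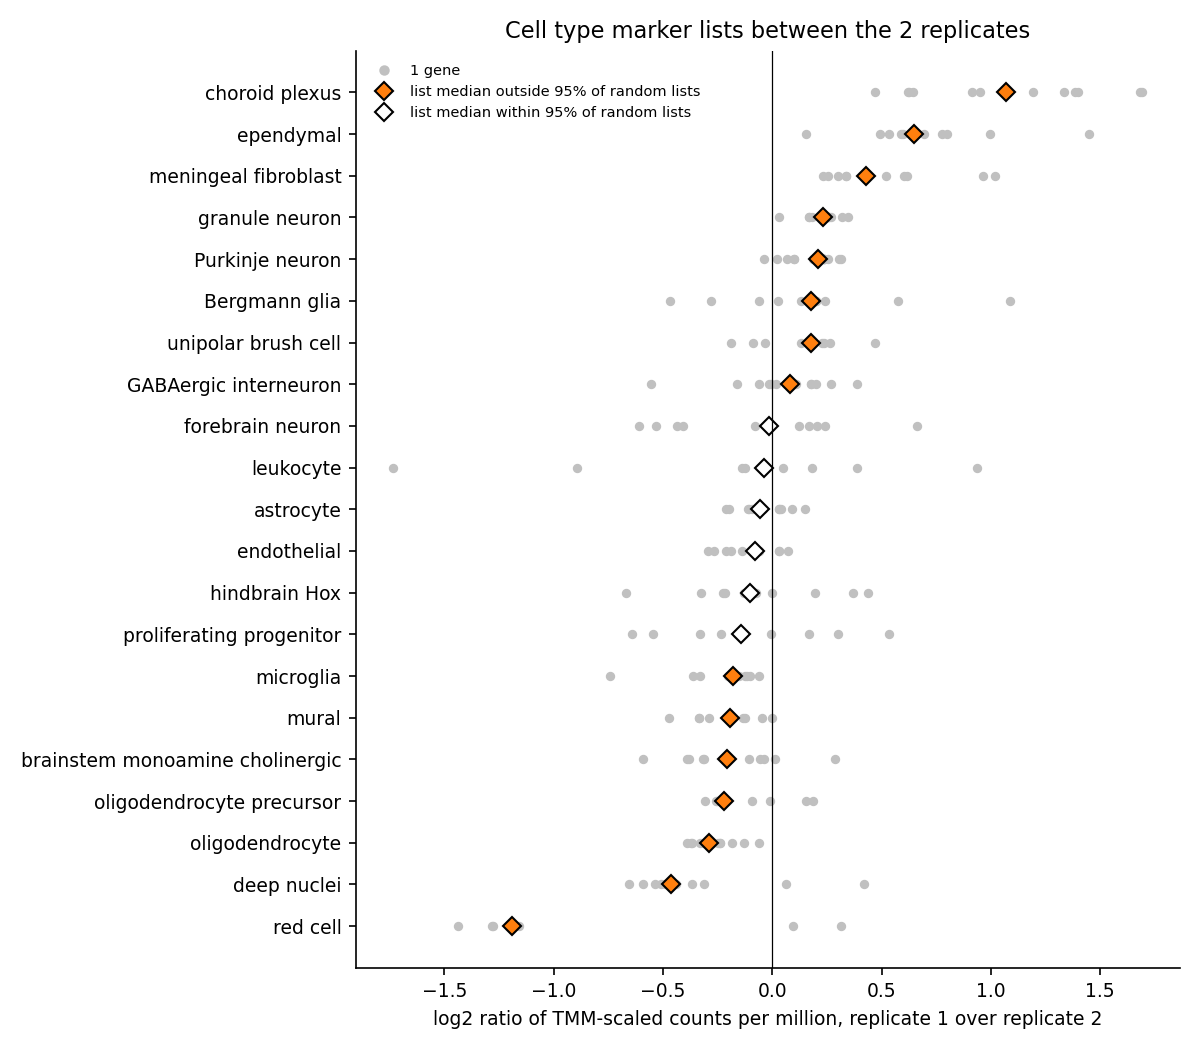
Log2 ratio of TMM-scaled CPM, replicate 1 over replicate 2, for genes (grey) and medians (diamonds) of the cell type lists. Filled diamonds lie outside the central 95% of matched random lists, from 1.07 for choroid plexus to -1.19 for red cells.

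The same libraries had also been quantified by the authors on the older mm9 assembly with Ensembl 65. Its RPKM values carry replicate numbers 1 and 2 without naming a library. Over 33068 shared genes, TPM of replicate 1 had a Spearman rho of 0.917 with the RPKM numbered 1 and 0.921 with that numbered 2, and replicate 2 had 0.924 with the RPKM numbered 2 and 0.917 with that numbered 1; these are correlations across genes. Xist was at 14.4 RPKM under number 1 and 0.0532 under number 2, and Eif2s3y was listed at 0 under number 1 and at 6.14 under number 2. Over 11130 genes with at least 1000 counts, log2 ratios of 1 over 2 correlated between mm10 and mm9 with Pearson r 0.590. Swapped numbers would give that r the opposite sign. All 37 mitochondrial genes are listed at 0 in the mm9 gene table. By median RPKM, 5 of the cell type lists reached 10, and their order followed that of TPM (Spearman rho 0.983 over 21 lists), RPKM and TPM being on different scales.

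Splicing and unannotated transcription were described from the authors' mm9 junctions and contigs, the latter pooled over both replicates. The junction table held 1125475 junctions, and 943165 of them (83.8%) matched no Ensembl 65 intron. These held 4.78% of junction reads, and 75.8% of them rested on 1 read. Among junctions with at least 10 reads, 17.2% lay outside annotated introns. Of 243332 annotated introns, 74.9% were seen. Contigs overlapping exons on their own strand covered 317 Mb and held 82.2% of aligned bases, a mean of 124 aligned bases per covered base. Intronic contigs covered 345 Mb at a mean of 11.3 and held 8.10%, and contigs antisense to genes covered 32.6 Mb at a mean of 43.2 and held 2.93%.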

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

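The test of mt-Atp8 was chosen after its result was seen.

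Some signals appeared in data that the comparisons of annotated genes did not use. The phiX entry, a bacteriophage sequence used as a sequencing control, held 965660 expected counts in replicate 1 and 1513832 in replicate 2, although it is no part of the mouse transcriptome. Among loci assembled by the authors on mm9, 182 outside every Ensembl 65 gene reached 1 RPKM in both replicates, 3.98% of the 4569 loci at that level, and 33 reached 10 RPKM. The highest lay on mm9 chromosome 1, positions 24621719 to 24623071, at 1756 and 1929 RPKM, followed by chromosome 6, positions 3150768 to 3151736, at 310.3 and 282 RPKM. On mm10, nuclear copies of mitochondrial sequence lie on chromosome 1 between positions 24612407 and 24616197. Positions of the assemblies were not matched, so whether the highest locus holds mitochondrial reads was not tested. Intergenic contigs covered 109.9 Mb at a mean of 17.5 aligned bases per covered base and held 4.01% of aligned bases. Mitochondrial contigs held 2.78% of aligned bases on mm9, while the mm9 gene table lists all 37 mitochondrial genes at 0.

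The gene with the highest TPM in both libraries was mt-Atp8, at 118633 ± 20913 TPM. A candidate explanation is its short effective length, which the authors' table puts at 14.8 and 12.7 of 204 nucleotides. Per annotated base, mt-Atp8 had 0.426 and 0.479 times the counts of mt-Co1 in the lower and the higher of the 2 libraries, although its TPM was above that of mt-Co1 in both. At 399.8 and 464 counts per base in replicates 1 and 2 it was above its neighbour mt-Atp6 (349 and 392) and the other members apart from mt-Co1, mt-Co2, mt-Co3 and, in replicate 1, mt-Cytb. Reads shared with mt-Atp6, which it overlaps, and with nuclear copies stay open, and no biological explanation was tested.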

How the results depend on the processing

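Alternatives chosen after seeing the data were the GC and length correction, leaving out the sex-linked list, protein-coding genes only and leaving out 6 lists in the 2-fold count, the mm9 isoform shares, and junctions seen in both replicates. No paired analysis was possible because all samples belong to one group. Counts of genes 2-fold apart were 37 by TPM ratio and 635 with at least 10 counts (Poisson draws gave 204), against 99. They were 16 with at least 1000 counts and 421 at 1.5-fold. The filters test more or fewer genes and 1.5-fold is a lower threshold. The TPM ratio adds 1 to each value, which shrinks ratios of genes with low TPM, such as Drc7 at 2.69 and 1.23 TPM. How much of the drop to 37 this explains was not tested. DESeq2 size factors gave 99, spike-in totals 113, protein-coding genes 90, and leaving out the choroid plexus, ependymal, meningeal, red cell, leukocyte and sex-linked lists 80. Those 80 still hold choroid plexus markers outside the list, such as Cldn2 and Car12, and the sex-chromosome genes Mid1 and Gm29650. Leaving out short lists therefore does not take out every gene of those tissues or of the sex chromosomes. Pearson r between replicates was 0.988 with a pseudocount of 0.1, 0.963 with 0.01, 0.990 for genes at 1 TPM, 0.997 for protein-coding genes, 0.994 for rescaled TPM and 0.996 for FPKM. The coefficient of variation was 0.0975 without a filter and 0.0829 at 1000 counts. By mm9 RPKM, 5 cell type lists reached 10, on another scale. Genes with a second transcript numbered 1955 at 20 TPM, 5412 at 10% and 1222 at 30%. The correlation of mm9 with mm10 was 0.861 for genes above 1 in both and 0.906 above 0.1. Junctions outside introns were 56.8% at 2 reads, 17.2% at 10 and 39.4% in both replicates. For these the cause was not tested. Leaving out each replicate gave 14714 to 14851 detected genes, 10 to 11 lists at 10 TPM, 3672 to 3675 genes with a second transcript and a correlation of 0.917 to 0.924; it leaves no comparison between replicates.

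The number of lists standing apart was 28 with DESeq2 size factors, 27 by TPM, 27 with 100 counts, 22 by mm9 RPKM and 27 after the GC and length correction, and 27 without the sex-linked list; 20 of 28 stood apart in one direction under all 5 that recompute the ratios. Of single list ratios under these alternatives, 211 kept their sign and their side of the threshold, and 12, within the range of random lists both ways, changed sign. A further 11 moved into that range, and 3 moved out of it: endothelial (-0.07) and cerebellin and neurexin (0.18) lists by TPM, and forebrain neurons by mm9 RPKM (0.22), with a change of sign. Of lists that stood apart, 2 reversed: the mitochondrially encoded list by TPM (0.0057), where TPM moved the median of all genes by 0.06, and the sex-linked list by mm9 RPKM (0.91), where 3 members were above 0 in both. Of list levels, 69 moved by more than the spread of the replicates and 57 did not. Rescaled TPM, FPKM and mm9 RPKM put levels on another scale, so most of these had to move. Leaving out a replicate mostly shifts a level by less than that spread. These counts are therefore no measure of how stable the levels are. Depth limits ratios of genes near 100 counts.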

Other observations

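The GC and length correction and the test of scaling on cell type lists were chosen after seeing the data. The other tests of this section address patterns seen in the data but were set before their own results were seen.

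Other fixed programs describe the state of the tissue. Of the immediate-early genes, Dusp1 was at 41.8 ± 3.07 TPM, Jun at 35.7 ± 4.89 TPM, Arc at 21.2 ± 0.0636 TPM and Egr1 at 17.1 ± 1.49 TPM, around a median of 8.79 TPM, and Egr2 at 0.0850 ± 0.0636 TPM. Heat shock genes had a median of 64.3 TPM, led by the constitutive chaperone gene Hspa8 at 1751 ± 98.1 TPM and Hsp90aa1 at 385 ± 54.9 TPM, while the stress-inducible Hspa1b was lowest at 4.48 ± 2.21 TPM. Clock output genes Tef and Dbp stood at 183 ± 0.530 TPM and 164 ± 6.06 TPM, and Nr1d1 at 100.4 ± 12.6 TPM. The long non-coding RNAs Meg3, Malat1, Rian and Snhg11 were at 1313 ± 15.7, 1248 ± 113, 1201 ± 81.5 and 693 ± 39.8 TPM. Ribosomal protein genes had a median of 333 TPM, with Rplp1 at 1670.3 ± 34.4 TPM, and lipid synthesis genes one of 52.7 TPM, with Scd2 at 455 ± 19.5 TPM and Fasn at 162 ± 9.86 TPM. Replication-dependent histone genes had a median of 4.08 TPM, with Hist1h2bc at 131 ± 11.2 TPM. Between replicates the medians of immediate-early (0.06), heat shock (-0.03), clock (-0.06), long non-coding RNA (0.03), nuclear oxidative phosphorylation (-0.03) and glycolysis (0.03) genes lay within the central 95% of matched random lists. So did those of AMPA (0.11), NMDA (0.03) and metabotropic (0.06) receptors, sodium channels (-0.06), cerebellins and neurexins (0.06), synaptotagmins (0.04), Camk2 (0.10) and vesicle release genes (-0.04), although by TPM ratio cerebellins and neurexins lay outside it (0.18). The sign changed with the scaling for heat shock, clock, oxidative phosphorylation and vesicle release genes, and by mm9 RPKM it also changed for NMDA receptors (-0.11) and long non-coding RNAs (-0.05).

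Sex-linked transcripts split the replicates although both are labelled as pooled male and female. A difference in depth or scaling was argued against, since library totals and spike-ins differed by at most 0.0708 on the log2 scale. Tissue of one sex in each library predicted higher levels in replicate 1 of X-linked genes that escape inactivation, and 5 of 6 such genes were higher, with a median log2 ratio of 0.51 (Kdm6a 0.77, Eif2s3x 0.56, Utp14a -0.06). The split goes with replicate 1 being tissue of females and replicate 2 of males, a hypothesis under which the pooled label would describe neither. Over 4 Y-linked genes replicate 1 had 0 counts against 11890, and Xist in replicate 2 was at 0.0562% of replicate 1. As far as these genes go, that argues against tissue of both sexes in either library. Which animals went into each library is not given in the sources used here, and no biological explanation other than the sex of the animals was tested, since the design has one group.

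Cell type lists moved apart between the replicates. GC content or length was argued against as the whole cause: after correction the choroid plexus median was 1.08 and that of oligodendrocytes -0.28. So was one scaling factor per library, which shifts all lists alike, since the choroid plexus median lay 1.36 above that of oligodendrocytes and the lowest choroid plexus gene 0.53 above the highest oligodendrocyte gene. Different shares of attached tissue in the 2 dissections predicted the same direction in a second choroid plexus list sharing no gene with the first. That list had a median of 1.18 with 11 of 12 genes higher in replicate 1. Its most abundant gene, Igfbp2, at 51.5 and 40.0 TPM, differed least of those, by 0.30. A second list of brainstem and nuclei neurons was predicted to be higher in replicate 2. The median of these neurons was -0.30, with Nefl at 285 and 351 TPM. Second markers of the same tissue would follow the first under any cause that changes its amount. These results therefore cannot tell dissection from other causes. Deep cerebellar nuclei are also not attached tissue. Of the hindbrain Hox genes 8 of 11 were higher in replicate 2, but their median (-0.10) lay within the range of random lists. The sex of the animals, which would coincide with the library, stays open and untested, as does residual blood for the globins, and the smaller shifts of the other lists were not tested for a cause.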
